A study of Homo sapiens with 4 samples.

How the data were processed

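Blood leukocyte RNA of 4 kidney transplant recipients in acute rejection was hybridised to 4 2-colour spotted cDNA arrays, 1 recipient per array. The labels abbreviate the leukocytes as PBL, the usual short form for peripheral blood leukocytes or lymphocytes, and do not say which. Per the labels, the rejection RNA carried the dye Cy5 on every array. The dye Cy3 marked 1 common reference of the same kind of blood RNA, described as of day 7 and without rejection. No array carried the dyes the other way round, and no recipient without rejection was hybridised by itself.

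The values used were the deposited log ratios of the 2 channels, 1 per spot and array, taken here as log2. The labels and the table state neither the base of the logarithm, nor the direction of the ratio, nor any normalization. A base of 10 would need ratios wider than a scanner can record, whereas the natural logarithm cannot be excluded; every log2 value and fold below rests on base 2. The image software, background correction and spot filter are not given in the sources used here. Channel intensities were not analysed here, so signal over background is unknown and the number of arrays limits the precision. The deposited columns held values for 8890, 8877, 8948 and 8992 spots on replicates 1 to 4, with medians of 0.10, 0.15, 0.13 and -0.047, so the arrays had not been centred on the median of these spots. Their standard deviations (SD) were 0.73, 0.99, 0.79 and 0.91.

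Ratios were read as Cy5 over Cy3, that is, rejection over reference. This direction is not settled. Replicate 4 correlated below 0 with each of the other arrays over all spots (Pearson r = -0.20, -0.47 and -0.35 with replicates 1, 2 and 3), although the labels give it the same dyes, reference and condition. Replicates 1 to 3 correlated above 0 with one another (r = 0.36, 0.40 and 0.60). These are correlations across spots within arrays, and spots are not independent replicates. Counts of calls, list values and the named genes are therefore also given with the sign of replicate 4 turned, a setting chosen after seeing the data. If all 4 arrays held reference over rejection, every direction would be mirrored.

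The table held 9216 spots. A platform annotation gave 1 gene symbol to 4474 of them (3319 different genes), several symbols to 288 and none to 4454. Of the spots with 1 symbol, 4469 matched the GRCh38.p14 gene table by gene identifier and 0 symbols needed updating. No gene was named from a spot with several symbols, and a spot with no symbol is unnamed here, not without a gene. The X-inactivation transcript and Y-linked genes were removed, because the donors are patients, which left 9207 spots. Of the 9216, 41 had no value on any array and 8559 had a value on all 4.

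Each array was centred on its median. Spots naming the same single gene were averaged, which concerned 929 genes, and other spots were tested by themselves. Genes and spots with values on at least 3 arrays were tested in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, as the mean of the 4 arrays against 0, two-sided, with Benjamini-Hochberg adjustment and a threshold of adjusted p 0.05. The reference counts as 1 control sample, so a test of the ratio against 0 leaves out the spread between recipients without rejection. The 4 arrays held different recipients, per the labels. The fit was tested on simulated data with 200 of 7848 genes and spots changed. It recovered 0 at a log2 change of 1, 156 (78%) at 2 with 11 false calls, and 187 (93.5%) at 3 with 13 false calls. The simulated noise was independent between genes and arrays, without the opposition of replicate 4, so these rates may not hold for the real arrays.

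Before the data were examined, 25 gene lists of blood cell types, red cell and iron biology and immune pathways were fixed, together with the tests, the other settings to be tried and the rule for named genes. Lists with at least 5 genes measured, 12 of the 25, were tested with limma's cameraPR at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation was the alternative. It used only genes with values on every array of the fit, and its test has only the few degrees of freedom that the arrays leave. It therefore has little power here, and a call lost under it does not by itself show that correlation between genes accounts for the call. A list's value on an array is the median over its genes. Where genes were adjusted over a list alone, that adjustment does not allow for the number of lists. The genes of the 3 red cell lists, pooled, were tested by an exact two-sided sign-flip test over the 4 arrays, whose 16 sign patterns allow no p below 0.13.

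The rule named, per direction, the 12 genes with a symbol that had the largest mean log2 ratio and 1 sign on all arrays, those past the threshold first. Genes not past the threshold had to have a value on all 4 arrays. It added up to 4 members with the largest limma statistic from each list past its test and from the haem synthesis, red cell, iron and folate lists, and every haemoglobin chain that a spot named alone, of which there were 0. The same rule of 12 was applied with the sign of replicate 4 turned. Other members are named as examples of their lists, chosen after their values were seen. Genes of blood group and of common copy number polymorphism were not named.

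The other settings fixed in advance were no centring, scaling to equal spread, quantile normalization, a minimum of 4 or of 2 arrays, each probe by itself, robust variance moderation, the array pair as a random block, leaving out each array in turn, ranking only genes with a symbol, and the mean in place of the median. The pairs came from image numbers in the labels that fall in 2 runs of consecutive numbers, replicates 1 and 3 and replicates 2 and 4. Whether they mark a batch is not stated. Batch and group cannot be compared, because all 4 arrays belong to 1 group.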

Results

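Gene expression in blood leukocytes of 4 kidney transplant recipients in acute rejection was measured against 1 common reference of blood RNA. The reference was described as of day 7 and without rejection. The title of the series names anaemia in rejection, so the genes of red cells, haem and iron are the study's own question. Each of the 4 arrays gave between 8877 and 8992 log ratios. After spots of the same gene were averaged, 7848 genes and unnamed spots could be tested, of which 3295 carried a gene symbol. Values are log2 ratios, read as rejection over reference and given as mean ± SD over 4 arrays unless stated. The direction is not settled, because replicate 4 ran against the other 3 arrays.

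Among genes with a symbol that lay on the same side of 0 on all 4 arrays, the lowest was JCHAIN. It encodes the chain that joins immunoglobulin M and A into polymers. Its mean log2 ratio was -2.84 ± 0.62 (n = 4), a fold of 7.15 below the reference, and all 5 of its spots lay below 0 on all 4 arrays. PLXDC2, a membrane protein with a plexin-like domain, had -2.80 ± 0.79, and PHC2, a Polycomb group protein, -2.20 ± 0.26. Also among the 12 lowest were SLC25A37, which carries iron into mitochondria, at -1.66 ± 0.57, NFE2, a transcription factor of red cell and platelet precursors, at -1.16 ± 0.69, FERMT3, an activator of integrins in blood cells, at -1.10 ± 0.76, and LILRB2, an inhibitory receptor of myeloid cells, at -0.94 ± 0.51. The others were FAM76B (-1.74 ± 1.02), ELF3 (-1.27 ± 0.13), S100P (-1.17 ± 0.79), GPRASP1 (-0.94 ± 0.32) and RCOR1 (-0.94 ± 0.55). Of the 6 of these genes with several spots, 3 had spots on both sides of 0 on at least 1 array: ELF3, an epithelial transcription factor, on all 4, RCOR1 on replicate 4, and LILRB2 on replicate 4, at 0.21 and -0.63. With the sign of replicate 4 turned, the means moved toward 0 and spread more, as the choice of genes with 1 sign requires: -1.76 ± 2.64 for JCHAIN, -1.57 ± 2.79 for PLXDC2, -1.20 ± 2.14 for PHC2, -0.90 ± 1.71 for SLC25A37, -0.98 ± 0.99 for NFE2, -1.08 ± 0.80 for FERMT3 and -0.83 ± 0.71 for LILRB2. FAM76B then had -1.47, ELF3 -0.69, S100P -0.18, GPRASP1 -0.26 and RCOR1 -0.79.

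On the positive side the values were smaller and less even. The 12 had values on all 4 arrays, which left out BUB1B, with a mean of 1.74 over 3 arrays. Its values were 4.31, 0.50 and 0.40 on replicates 1, 2 and 4. KLHL13, an adaptor of a ubiquitin ligase, had 1.28 ± 1.51, and ENTREP2 had 1.21 ± 1.28. RSAD2, an antiviral gene induced by interferon, had 0.92 ± 0.69 and was above 0 on all 4 arrays as read. NRF1, a transcription factor of mitochondrial genes, had 0.89 ± 1.32, FBLN1, a protein of the extracellular matrix, 0.84 ± 0.63, and NELL2 0.70 ± 0.98. The mitochondrial ribosomal gene MRPS31 (0.69 ± 0.44), APBB3 (0.69 ± 0.32), the deubiquitinase USP15 (0.64 ± 0.88), the potassium channel KCNH7 (0.63 ± 0.13), SSX3 (0.62 ± 0.79) and CHST1 (0.62 ± 0.66) completed the 12. Of the 7 with several spots, 6 had spots on both sides of 0 on at least 1 array, namely ENTREP2, NRF1, FBLN1, USP15, SSX3 and CHST1. Several of these means rested largely on 1 array. KLHL13 had 3.43 on replicate 4, and its mean was -0.44 ± 2.05 with replicate 4 turned and 0.56 without it. RSAD2 had -0.046 ± 1.27 turned and 0.58 without replicate 4, and NELL2 -0.37 ± 1.198 and 0.22. Without replicate 1, NRF1 had 0.23 and FBLN1 0.55. Without replicate 2, ENTREP2 had 0.70, USP15 0.21, SSX3 0.23 and CHST1 0.30. The turned means of the others were 1.17 for ENTREP2, 0.80 for NRF1, 0.43 for FBLN1, 0.065 for MRPS31, 0.38 for APBB3, 0.62 for USP15, 0.41 for KCNH7, 0.56 for SSX3 and 0.53 for CHST1.

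No gene passed the threshold in limma in either direction (0 higher, 0 lower). With the array pair as a random block, 14 passed as lower and 0 as higher in limma, among them JCHAIN (adjusted p = 0.0095), PHC2 (0.0092) and PLXDC2 (0.036). The within-pair correlation in that fit was -0.43, and a negative one narrows the standard error of each mean. Over all spots, the pair of replicates 2 and 4 correlated at -0.47 and that of replicates 1 and 3 at 0.40. In the fit without blocks, 308 had an unadjusted limma p below 0.05, of which 242 were lower. That is fewer than the 0.05 share of the 7848 tested that independent arrays without any change would give. Replicate 4 opposed the others, and turning the signs of whole arrays in 8 ways, as read included, moved that count between 51 and 2524. The shortfall in the fit as read is therefore no measure of signal. The smallest adjusted p was 0.065, that of JCHAIN, PHC2 and 5 unnamed spots; PLXDC2 had 0.114 and SLC25A37 0.40. These 7, all lower, were the only ones with an adjusted p under 0.10. Without replicate 4, limma called 16 of 7640 lower and 0 higher, among them JCHAIN (-3.07), PHC2 (-2.27), SDCBP and GCA. Each of the 12 genes named on the positive side had an adjusted p of 0.9995 in limma.

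**Figure D1:**
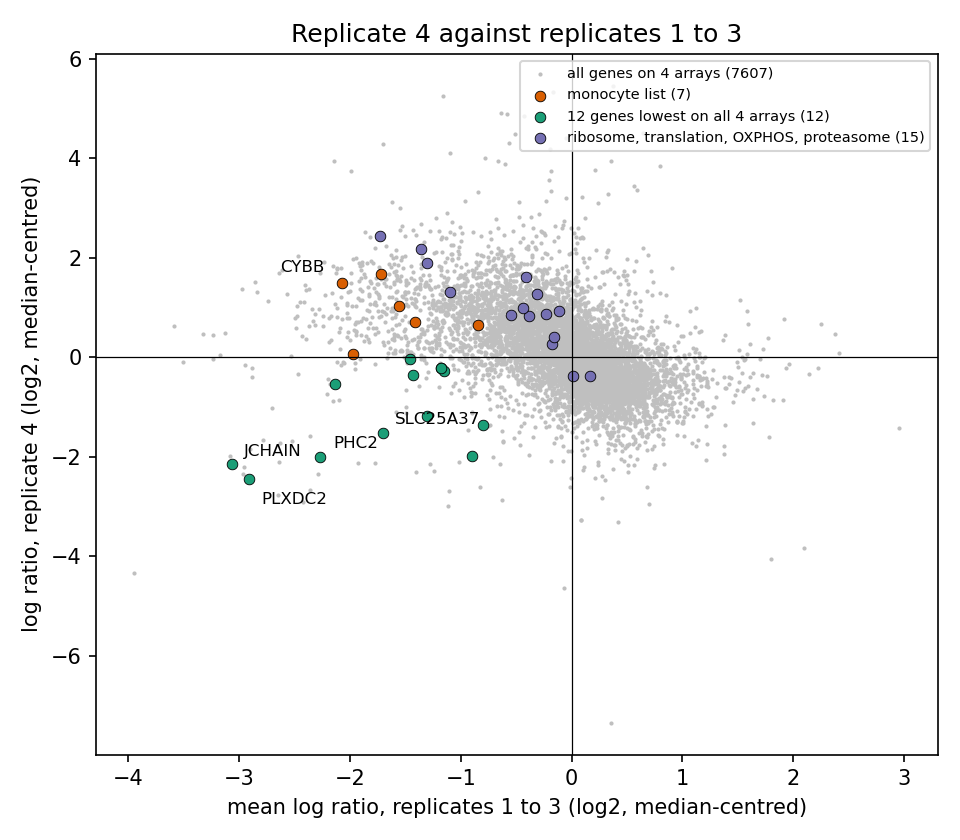
Each point is 1 of 7607 genes or unnamed spots measured on all 4 arrays, with the mean median-centred log2 ratio of replicates 1 to 3 on the horizontal axis and that of replicate 4 on the vertical axis. Most of the spread runs from upper left to lower right, whereas the 12 genes lowest on all 4 arrays (green) lie at lower left and the 7 monocyte genes (orange) at upper left, above 0 on replicate 4 except LILRB2.

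The arrays split by sign for many genes. Of 7607 genes and spots measured on all 4 arrays, replicate 4 lay opposite to 3 agreeing arrays in 3394 (44.6%), where independent signs would give 12.5%. Values below 0 on all 4 arrays were found for 322 (4.23%) and above 0 for 296 (3.89%), against 6.25% each for independent signs. At the same time, 25 lay below -1 on all 4 arrays, where independent arrays with the same distributions would give 0.341. Above 1 on all 4 arrays lay 0, where such arrays would give 0.067. With the sign of replicate 4 turned, 1722 (22.6%) lay below 0 and 1672 (22.0%) above 0 on all 4, 68 below -1 and 4 above 1.

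Over the 12 measured genes of haem synthesis and of the red cell membrane and erythroid lists, the median of the centred arrays was -0.36, -0.053, -0.29 and -0.39 on replicates 1 to 4, with a mean of -0.27 ± 0.15. The exact two-sided sign-flip test gave p = 0.13, the smallest that 4 arrays allow. Without centring, the median on replicate 2 was above 0, at 0.10, the mean was -0.19 ± 0.22 and the exact p 0.25. With the sign of replicate 4 turned, the mean was -0.079 ± 0.34, and without replicate 4 it was -0.23 ± 0.16. No haemoglobin chain was named alone by a spot, so the haemoglobin chains were not analysed here.

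Of the 4 measured genes of haem synthesis, 3 had negative means. SLC25A37 was the lowest, FECH, which inserts iron into the porphyrin ring, had -0.44 ± 0.21 and was below 0 on all 4 arrays, and ABCB10, a mitochondrial transporter, had -0.25 ± 0.29. SLC25A38, a mitochondrial carrier of glycine, had 0.10 ± 0.41. With p-values adjusted over the list alone, 1 of the 4, SLC25A37, passed in limma, and 0 passed with replicate 4 turned, where SLC25A37 had -0.90 ± 1.71 and FECH -0.31 ± 0.41. The list median was -0.37 ± 0.23 (-0.35 ± 0.28 with replicate 4 turned) and was not tested, as it had fewer than 5 genes.

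Of the 8 red cell membrane and erythroid genes, 7 had negative means and 0 passed, also when adjusted over the list alone. NFE2 was followed by LMO2, a cofactor of early blood cell development, at -0.58 ± 0.88, ANK1, the ankyrin of the red cell membrane, at -0.26 ± 0.39, and BNIP3L, which clears mitochondria from maturing red cells, at -0.19 ± 0.39. KLF1, a master regulator of erythroid genes, had 0.066 ± 0.58. The median of the list was -0.12 ± 0.37, at -0.069, 0.34, -0.19 and -0.57 on replicates 1 to 4, and limma's cameraPR gave an adjusted p of 0.168. With replicate 4 turned the median was 0.16 ± 0.35 (adjusted p = 0.92), LMO2 passed in limma at -0.93 ± 0.24 (adjusted p = 0.045), the only member to pass adjusted over the list alone, and NFE2, ANK1, BNIP3L and KLF1 had -0.98, 0.094, -0.11 and 0.44. Without replicate 2, cameraPR placed the list below other genes at a median of -0.28 (adjusted p = 0.0347), and the adjusted p was 0.998 with an estimated correlation in the same 3 arrays.

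Of 9 iron handling genes, 6 had negative means and 0 passed, also when adjusted over the list alone. NCOA4, the receptor that delivers ferritin for breakdown, had -1.56 ± 1.85, at -1.76, -2.98 and -2.61 on replicates 1 to 3 and 1.11 on replicate 4. CD163, the scavenger receptor for haemoglobin, had -0.53 ± 0.21 and was negative on all 4 arrays. SLC40A1, the iron exporter ferroportin, had -0.36 ± 0.40, and HFE, a regulator of iron uptake, had 0.31 ± 0.18. The list median was -0.12 ± 0.10 (cameraPR adjusted p = 0.78), and with replicate 4 turned -0.089 ± 0.14 (0.52), where NCOA4 passed in limma at -2.11 ± 0.84 (adjusted p = 0.045) and CD163, SLC40A1 and HFE had -0.33 ± 0.52, -0.13 ± 0.55 and 0.29 ± 0.23. Adjusted over the list alone, 2 of the 9 then passed.

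The 5 genes of folate and cobalamin handling went both ways, 2 negative and 3 positive, and none passed in limma, also when adjusted over the list alone. SLC46A1, the intestinal folate carrier, had 0.19 ± 0.62, SLC19A1, the reduced folate carrier, 0.11 ± 0.66, SHMT1 -0.098 ± 0.38 and SHMT2 -0.19 ± 1.04, both enzymes of the folate cycle. The list median was 0.076 ± 0.61 (cameraPR adjusted p = 0.95) and 0.37 ± 0.45 with replicate 4 turned (0.37), where SLC46A1, SLC19A1, SHMT1 and SHMT2 had 0.48, 0.46, 0.17 and 0.53. The 10 genes of erythropoietin and hypoxia signalling were split 5 to 5, with a median of 0.029 ± 0.18 (adjusted p = 0.95) and -0.040 ± 0.18 with replicate 4 turned (0.92). Among them EGLN3, an oxygen sensor, had 0.32 ± 0.43, and CSF2RB, a shared cytokine receptor chain, -0.61 ± 0.92 (0.36 and -0.94 turned). When turned, 3 of the 10 passed adjusted over the list alone and 0 over all genes, and 0 folate genes passed either way.

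The monocyte list was the only one of the 12 tested that passed, as lower (cameraPR adjusted p = 7.98e-05), and its adjusted p was 0.93 with an estimated correlation. Its 7 measured genes all had negative means, and its median was -1.08 ± 1.28, at -0.98, -1.99, -2.05 and 0.70 on replicates 1 to 4. TYROBP, a signalling adaptor of myeloid receptors, had -1.46 ± 1.14; CYBB, a subunit of the phagocyte oxidase, -1.18 ± 1.88; LILRB2, -0.94 ± 0.51; and CCR2, the chemokine receptor of inflammatory monocytes, -0.89 ± 1.27. Each of these genes was below 0 on replicates 1 to 3, and of them LILRB2, as the mean of 2 disagreeing spots, was also below 0 on replicate 4. The estimated correlation between its genes was 0.87. No member passed in limma by itself, also when adjusted over the list alone. With replicate 4 turned the median was -1.43 ± 0.69 (cameraPR adjusted p = 4.28e-05, adjusted p = 0.55 with an estimated correlation), 2 members passed over all genes and 7 of 7 adjusted over the list alone. TYROBP, CYBB, LILRB2 and CCR2 then had -1.497, -1.93, -0.83 and -1.24. Without replicate 4 the median was -1.67 ± 0.60 (adjusted p = 1.37e-06).

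**Figure D2:**
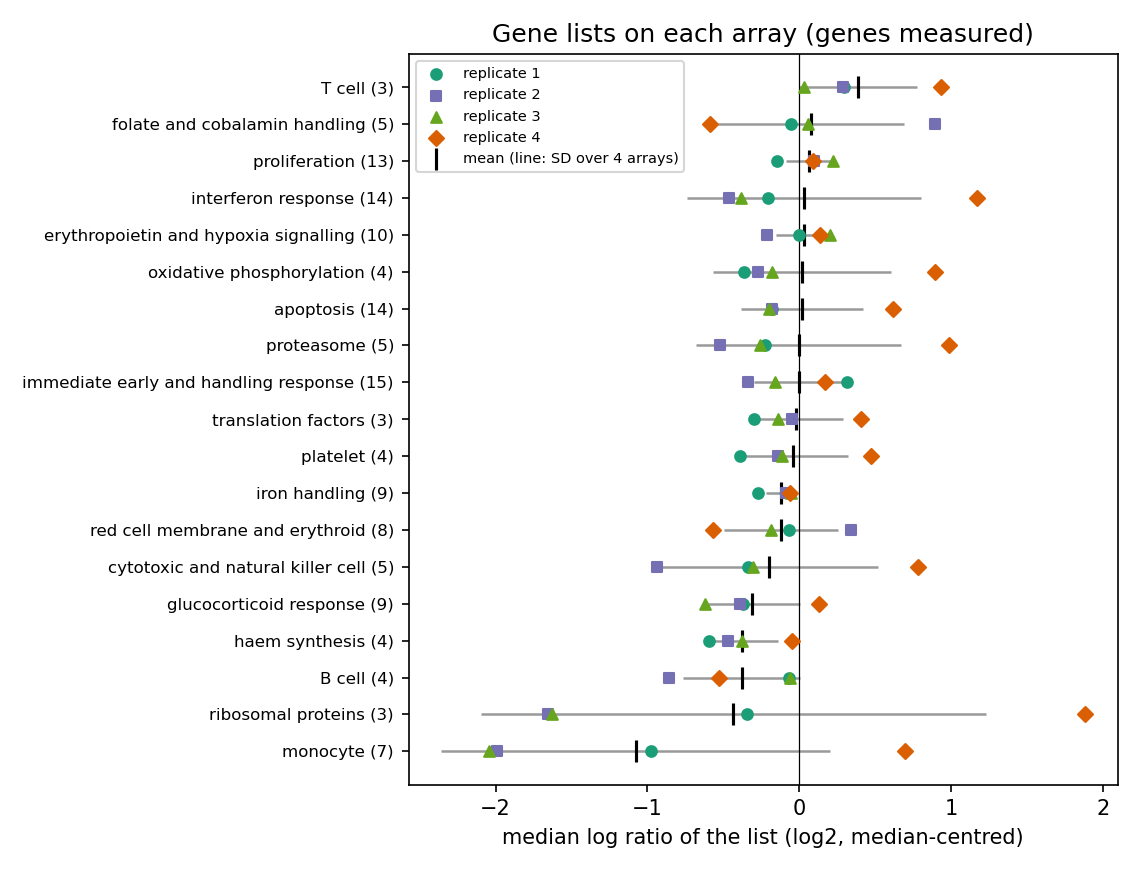
Each row is 1 gene list with its number of measured genes in brackets, and each symbol is the list's median log2 ratio on 1 array, with the mean of the 4 arrays as a black bar and their SD as a grey line. The monocyte list lies at -0.98, -1.99 and -2.05 on replicates 1 to 3 and at 0.70 on replicate 4; the interferon list lies below 0 on replicates 1 to 3 and at 1.17 on replicate 4.

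Of the 14 genes of the interferon response, 11 (78.6%) lay on opposite sides of 0 on replicate 4 and on all 3 other arrays, against 44.6% of all genes and spots, a difference not tested. The median of the 14 genes was -0.20, -0.46 and -0.39 on replicates 1 to 3 and 1.17 on replicate 4, with 7 positive and 7 negative means. RSAD2, named above, was not on this list and lay above 0 on replicates 1 to 3 as well as on replicate 4. IFI44L, an interferon-induced gene, had 0.66 ± 1.21 with 2.40 on replicate 4, and IFIT2, an antiviral protein, 0.31 ± 1.35 with 2.32 there. BST2, which tethers viruses to the cell surface, had -0.77 ± 1.76. None passed in limma, also when adjusted over the list alone. Over the 4 arrays the median averaged 0.031 ± 0.77 (cameraPR adjusted p = 0.95). With replicate 4 turned it was -0.56 ± 0.43 and passed as lower (adjusted p = 0.0045, adjusted p = 0.55 with an estimated correlation), and IFI44L, IFIT2 and BST2 had -0.54, -0.85 and -1.68. BST2 then passed over all genes in limma (adjusted p = 0.045), and 6 of the 14 adjusted over the list alone.

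Of the 9 glucocorticoid response genes, 6 had negative means and 0 passed, also when adjusted over the list alone. ANXA1, an anti-inflammatory protein, had -1.60 ± 1.85, TXNIP, a redox regulator, -1.28 ± 2.28, and BCL6, a transcriptional repressor, -0.58 ± 0.40. The 9 genes had a median of -0.31 ± 0.32 (cameraPR adjusted p = 0.168), and -0.38 ± 0.20 with replicate 4 turned (0.143), where ANXA1, TXNIP and BCL6 had -2.12, -2.13 and -0.53, ANXA1 passed over all genes and 3 of the 9 adjusted over the list alone. The 5 cytotoxic and natural killer genes had a median of -0.20 ± 0.72 (-0.59 ± 0.32 turned), with SRGN, a granule proteoglycan, at -1.68 ± 1.87 and GZMK, a granzyme, at 0.54 ± 0.59 (-2.07 and -0.16 turned). The 13 proliferation genes had 0.064 ± 0.15 (0.020 ± 0.17 turned), and the 15 immediate early genes -0.0037 ± 0.30 (-0.088 ± 0.28 turned). The adjusted p of these 3 lists was at least 0.93 in cameraPR, and 0.36 for the cytotoxic list and 0.92 for the other 2 with replicate 4 turned. As read, no member of the 3 passed, also when adjusted over the list alone. After turning replicate 4, the proliferation gene RFC3 passed over all genes, and 2 cytotoxic, 2 proliferation and 0 immediate early genes passed adjusted over their list alone.

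The 14 apoptosis genes had a median of 0.017 ± 0.40 and the 5 proteasome genes -0.0037 ± 0.67, each with a cameraPR adjusted p of 0.95 and 0 members past the threshold, also when adjusted over the list alone. With replicate 4 turned both passed as lower, apoptosis at -0.29 ± 0.22 (adjusted p = 0.018) and proteasome at -0.50 ± 0.35 (adjusted p = 0.019), and neither with an estimated correlation (adjusted p = 0.55 for each). Of their members, the apoptosis genes MCL1 (-1.54), TNFSF10 (-1.16) and CASP10 (-0.98) and the proteasome gene PSMA1 (-1.15) then passed over all genes in limma, and 3 and 2 adjusted over the list alone. For the erythropoietin and hypoxia, interferon, apoptosis and immediate early lists, the median, the mean over genes and the direction of the test did not all have the same sign.

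With the sign of replicate 4 turned, limma called 316 genes and unnamed spots lower and 23 higher, of which 122 and 4 had a symbol. Among genes past the threshold with 1 sign on all arrays, the lowest 12 were the actin-bundling protein LCP1 (-2.13 ± 1.05), the actin-capping subunit CAPZA1 (-1.998 ± 0.817), the actin-nucleation subunits ARPC5 (-1.83 ± 0.63) and ARPC2 (-1.75 ± 0.81), the scaffold protein SDCBP (-2.40 ± 0.59), ANXA1 (-2.12 ± 0.93), NCOA4, the autophagy protein GABARAP (-1.95 ± 0.93), CYBB (-1.93 ± 0.65), the splicing factor HNRNPH1 (-1.91 ± 0.44), the respiratory subunit NDUFA13 (-1.86 ± 0.65) and BTF3 (-1.76 ± 0.81). Their adjusted p lay between 0.045 and 0.048. Higher past the threshold were ANK3 (1.04 ± 0.32), the zinc transporter SLC39A2 (0.86 ± 0.26), the cytokine OSM (0.79 ± 0.14) and SIMC1P1 (0.77 ± 0.14), with adjusted p between 0.045 and 0.048. GYG2, WDR82, GCKR, KISS1, HSPB8, TM4SF18, COL1A1 and NAP1L3 had larger turned means, from 1.14 to 1.72, and did not pass. JCHAIN and PHC2 did not pass with replicate 4 turned. Of the 16 calls made without replicate 4, 2 were among these 339.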

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

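On 8 of 87 lists and genes checked, 1 of the 4 arrays lay far from the other 3 by Dixon's criterion, which chance alone meets for about 5% of groups. All tests of explanations given here were chosen after the results were seen. The interferon response list had 1.17 on replicate 4, against -0.46 to -0.20 on the others. The apoptosis list had 0.62 on replicate 4, against -0.20 to -0.18. The oxidative phosphorylation list had 0.89 on replicate 4, against -0.36 to -0.18. The cytokine OSM had -0.91 on replicate 4, against 0.65 to 0.92, and SIMC1P1 -0.86, against 0.61 to 0.90. Both were named because they passed with replicate 4 turned, so their distance from the other arrays follows in part from that choice. The iron handling list had -0.27 on replicate 1, against -0.088 to -0.056. NRF1 had 2.85 on replicate 1, against 0.12 to 0.40, and SSX3 had 1.79 on replicate 2, against 0.13 to 0.38. For NRF1 the value came from 1 of 2 spots, at 5.65 against 0.060 on the other spot.

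Of the 8, 5 lay on replicate 4, the array that opposed the other 3 in 44.6% of genes and spots. If its channels had simply been exchanged, with no dye bias of single transcripts, nearly all spots far below 0 on replicates 1 to 3 would lie above 0 on replicate 4, but 57.9% of the 57 spots under -1.5 on each of those arrays were below 0 there too (exact 95% binomial interval 44.1% to 70.9%). The interval takes spots as independent. They include several spots of the same gene, among them all 5 of JCHAIN, so it may be too narrow. An exchange together with a dye bias of some transcripts cannot be told apart from a real difference, because no sample was hybridised with both dye orientations. Turning replicate 4 gave 339 calls, whereas none of the other 7 sign patterns gave any. Turning it aligns it with the other arrays whatever the cause, so that count does not bear on an exchange. A candidate explanation that stays open is that abundant transcripts and spots with little signal were pulled apart by how the channels were scaled or labelled. The median of 15 ribosomal, translation, oxidative phosphorylation and proteasome genes minus that of 43 genes of tissues other than blood was 1.54 (log2) on replicate 4 and -0.47, -0.80 and -0.54 on replicates 1 to 3. With an exchange of channels or a real difference, that contrast would also turn on replicate 4, because this array opposed the others. It therefore favours none of these, and the signal of the 43 genes is unknown without channel intensities. No biological explanation was tested, since the labels put all 4 arrays in 1 group.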

How the results depend on the processing

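The sign of replicate 4 turned, and the estimated correlation without replicate 2, were chosen after seeing the data, and the other settings were fixed before the data were examined. Under the 16 settings fixed in advance, 914 of 924 recomputed values of genes and lists kept their side of the threshold and 10 crossed it, 9 gained calls and the monocyte call lost with an estimated correlation. The count of genes and spots called lower, 0, became 10 with quantile normalization and 14 with the array pair as a random block (within-pair correlation -0.43), and ranged from 0 to 16 when 1 array was left out, the 16 being without replicate 4. JCHAIN and PHC2 passed in each of these 3 settings, with limma adjusted p of 0.045 and 0.042, 0.0095 and 0.0092, and 0.038 each. No setting fixed in advance called a gene higher. The count of lists called lower, 1, became 0 with an estimated correlation, where the monocyte list kept its median of -1.08 at an adjusted p of 0.93. It ranged from 1 to 2 when 1 array was left out, the red cell membrane list (-0.28) being added without replicate 2 at the preset correlation; with an estimated correlation in those 3 arrays, 0 lists were called and that list had an adjusted p of 0.998. The monocyte median itself ranged from -1.67 to -0.76 in those fits and stayed past the threshold at the preset correlation. No list passed with an estimated correlation as read, without replicate 2 or with replicate 4 turned. For the red cell membrane list as read, the estimated correlation was -0.0049, below the preset 0.01. Its unadjusted p nevertheless rose from 0.042 in cameraPR to 0.122 in camera. With so few arrays, calls lost under that setting do not show that correlation between genes accounts for them. With replicate 4 turned, 316 were lower and 23 higher, 4 lists were lower (each at an adjusted p of 0.55 with an estimated correlation), and the interferon list went from 0.031 to -0.56. Of 75 values, 55 kept their side and 20 moved. The 75 include genes named because they passed with replicate 4 turned, so the share that moved follows in part from that choice. The cause was not tested for the changes between settings, except that a turned sign by construction aligns the array that opposed the others. A negative within-pair correlation likewise by construction narrows the standard error of each mean. The pooled red cell median ranged from -0.37 to -0.19 over the settings with 4 arrays fixed in advance and from -0.34 to -0.23 with 1 array left out, and was -0.079 with replicate 4 turned. Leaving out the haemoglobin chains moved nothing, as no spot named one alone. Without centring the pooled red cell median was above 0 on replicate 2 (0.10), and each array was shifted by its own median, at most 0.15. Channel intensities were not analysed here, so the limit that signal over background sets is unknown, and 4 arrays recovered no simulated change of 1 (log2).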

Other observations

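Lists with fewer than 5 measured genes were not tested as lists. Of the 4 B cell genes measured, 3 had negative means: TCL1A, a coactivator of kinase signalling in naive B cells, had -0.86 ± 0.33 (SD, n = 4) and was below 0 on all 4 arrays, CD79B, a chain of the B cell receptor, had -0.42 ± 0.34, likewise below 0 on all 4, and SPIB, a B cell transcription factor, had -0.41 ± 0.58. The activation marker CD83 had 0.22 ± 0.24. The list median was -0.38 ± 0.39 (-0.11 ± 0.57 with replicate 4 turned), and 1 of the 4 genes, TCL1A, passed in limma adjusted over the list alone. Turned, 0 of the 4 passed, and TCL1A had -0.51 ± 0.86, CD79B -0.24 ± 0.52, SPIB 0.010 ± 0.75 and CD83 0.15 ± 0.30. JCHAIN, the 1 measured gene of the plasma cell list, had an unadjusted limma p below 0.05 as read and not with replicate 4 turned. With 1 gene there is nothing to adjust over, and over all genes its limma adjusted p was 0.065 as read. The 3 T cell genes had a median of 0.39 ± 0.39, positive on all 4 arrays (-0.081 ± 0.58 turned), with LEPROTL1 at 0.43 ± 0.37, CD5, a T cell surface receptor, at 0.19 ± 0.16, and CD4 at -0.15 ± 1.11 (-0.038, 0.15 and -0.86 turned). Of the 2 T cell activation genes, STAT4, which transmits interleukin-12 signals, had -1.23 ± 1.75 and IL18R1 0.077 ± 0.19 (list median -0.58 ± 0.92, turned -0.84 ± 0.58, with STAT4 at -1.75 and IL18R1 at 0.057). Turned, 1 T cell gene and 1 T cell activation gene passed adjusted over their lists alone, against 0 as read.

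Both neutrophil genes had negative means, CSF3R, the receptor of the granulocyte growth factor, at -0.81 ± 0.91 and CEACAM6 at -0.28 ± 0.62 (list median -0.55 ± 0.49, turned -0.012 ± 0.80, with CSF3R at -0.29 and CEACAM6 at 0.27). The 4 platelet genes had a median of -0.043 ± 0.37 (turned -0.28 ± 0.18), with NRGN at -0.87 ± 1.05 (turned -1.13 ± 0.64). The 3 ribosomal protein genes had -0.44 ± 1.66, at -0.35, -1.65 and -1.63 on replicates 1 to 3 and 1.88 on replicate 4 (turned -1.38 ± 0.70). The 3 translation factor genes had -0.020 ± 0.30 (turned -0.22 ± 0.16), the 4 oxidative phosphorylation genes 0.018 ± 0.59 (turned -0.43 ± 0.32), and the 2 genes of inflammatory cytokines and NF-kappaB 0.16 ± 0.21 (turned 0.20 ± 0.15). As read, none of these 6 lists had a gene past the threshold adjusted over the list alone in limma. Once turned, 2 ribosomal genes, 1 platelet, 1 translation factor and 1 oxidative phosphorylation gene passed adjusted over their lists alone, and RPL31 and EIF3E also over all genes. No HLA gene was named alone by a spot, so the HLA list was not analysed here.

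All tests in the rest of this part were chosen after the results were seen. The B cell genes raised the hypothesis that transcripts of the B lineage may be lower in the rejection samples, beyond JCHAIN, which drew attention to them. Tested by itself and with no adjustment over lists, limma's cameraPR placed the B cell list below other genes at p = 0.0157, and a two-sided permutation test against 100000 random lists of as many genes gave p = 0.020, without allowing for correlation between genes. The camera p was 0.133 with an estimated correlation, between 0.0059 and 0.36 when 1 array was left out, the 0.36 being without replicate 4 and 0.086 without replicate 2, and 0.88 with replicate 4 turned. Without replicate 4 the list median was -0.33 ± 0.46, close to the -0.38 of all 4 arrays. With p above 0.05 with an estimated correlation, without replicate 2 or 4 and with replicate 4 turned, the tests do not settle whether the list lay below other genes. CD83, the member with a positive mean, also belongs to the list of inflammatory cytokines and NF-kappaB.

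The 12 lowest genes were chosen for lying below 0 on all 4 arrays, with replicate 4 as read. With each gene's lowest spot removed, 5 of the 6 with several spots still averaged below -0.5. Single bad spots do not account for JCHAIN (-2.61), PLXDC2 (-2.73) and PHC2 (-1.98), whose spots all lay below 0 on all 4 arrays. ELF3 was then at -1.01, RCOR1 at -0.81 and LILRB2 at -0.49. Those last genes had spots on both sides of 0, so removing 1 spot does not settle them. A dye bias of the 12 lowest transcripts, or a reference rich in them, cannot be told apart from lower expression in the rejection samples. Every array had the same dye orientation and the same reference. Of the 12 lowest genes, 6 had a value within 1 SD of 0 on some array by their own SD over the arrays. By the SD of the array, 7 did. This decides nothing, since recipients can differ on top of a constant bias. A difference between recipients with and without rejection stays open as well and was not tested beyond the ratio itself. The reference is described as of day 7, and a difference in sampling day was not tested either.

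The monocyte list was low on replicates 1 to 3, and whether a shift shared by all abundant transcripts placed it there stays open. Its median lay below that of the 15 ribosomal, translation, oxidative phosphorylation and proteasome genes by -0.68, -1.55 and -1.79 on the 3 arrays, -2.58 standard errors on the nearest. Against the 3 ribosomal genes alone, the differences were -0.63, -0.34 and -0.42, only -0.33 bootstrap standard errors on the nearest array, so the result depends on which abundant genes are compared. A shared shift cannot be told apart from fewer monocytes, lower expression per monocyte or a reference rich in monocyte RNA, because neither channel intensities nor cell counts were used here.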
